A study of Homo sapiens with 6 samples.

How the data were processed

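Libraries prepared from total RNA of 6 Jurkat samples, 3 with a scrambled sequence and 3 with a hairpin against NSUN2, had been sequenced by the submitters. The authors deposited raw read counts per gene for 17922 protein-coding genes, as whole numbers, per the file headers. Per the submitters' processing notes, the tools used were cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR, with genome build hg19. The gene annotation and whether counting used strand are not given in the sources used here, so overlapping and antisense genes, paralogs and pseudogenes can share reads in these counts. Normalised values by the authors (6 columns) and any comparison table of theirs were not used here. One line of the table was empty and was skipped.

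Samples were grouped by their titles. Total counts ran from 27149125 to 36847621 per library. Pairs of libraries of 1 group differed far beyond sampling noise (chi-square over degrees of freedom from 21.4 to 134), so each library was counted as its own sample. Symbols shared by several gene IDs (22 symbols) were kept apart by ID.

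Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12230 genes and removed 5692, of which 1191 had no read in any library. Libraries were scaled by TMM, with factors from 0.956 to 1.04. Dispersions and the quasi-likelihood fit were robust, the model held the group alone, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.246. Reported CPM are counts scaled by TMM and library size, log2 CPM used a prior count of 2, and the standard error of a log2 fold change was taken from the F statistic.

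A total of 30 gene lists, with 867 of 886 entries found in the table, were fixed before the data were examined, along with the tests, the main alternatives and the rule for naming genes. The 26 lists with at least 5 tested members were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, again with the estimated correlation, and with fry. Genes are named if they are NSUN2, 1 of up to 10 genes per direction with the largest log2 fold change past the threshold at a mean of at least 5 CPM with no overlap of the groups, 1 of the 5 with the smallest p per direction, a passing list member or otherwise the 2 members with the smallest p, or a control of the line (MYC, NOTCH1, BCL2, CDKN1A). Some genes that the rule names are not reported here. Members named beyond this rule are marked in the text.

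Alternatives were DESeq2 1.42.0 size factors, library totals alone, no filter beyond 1 read, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, each library left out in turn, a threshold of 0.01, the replicate number as a block, camera on ranks, and, chosen after seeing the data, edgeR's exact test, 1 surrogate variable from sva 3.50.0 and both libraries of 1 number left out. A pseudocount alternative was not needed, since the table holds counts. All 10 splits of the 6 libraries into 3 and 3 were also fitted. GC content, length and 3' untranslated regions came from the longest protein-coding transcript in GENCODE release 29, matched on the gene ID, with a value for 97.6% of tested genes (97.0% for 3' regions). That release is on another genome build, so no coordinates are given. In tests of words in 3' regions, the 7-base words held by at least 50 genes were compared with 100 shuffles.

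The tests of genes and of gene lists were run on simulated counts with known changes. With 200 changed genes, each with a mean over 100 reads, planted in each of 5 simulated sets of 12230 genes, edgeR's quasi-likelihood test recovered 15.6% of those changed 1.5-fold, 66.0% at 2-fold, 90.4% at 3-fold and 98.4% at 4-fold, with 48 false calls over the 5 sets. Over the same sets DESeq2 made 218 false calls and edgeR's exact test 194. A list shifted by 0.3 (log2), more than the median of any list called here, was called in 5 of 5 sets. Simulated genes varied independently, while the 4 lists called here had estimated correlations from 0.087 to 0.480. These figures therefore check how the tests of genes and lists were run and do not give the power or the false calls in the real data.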

Results

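RNA sequencing was used to compare Jurkat cells in which NSUN2 was silenced with control cells. Jurkat is an established human T-cell acute lymphoblastic leukaemia line, and NSUN2 encodes an RNA methyltransferase that places 5-methylcytosine on tRNAs and other transcripts. Lentiviral vectors carried either a short hairpin RNA against NSUN2 (shNSUN2) or a scrambled sequence, and each group had 3 libraries prepared from total RNA. The labels mark the hairpin as #2, and any other hairpin was not analysed here. The table held raw read counts for 17922 protein-coding genes. The scrambled libraries held 36847621, 34272640 and 33250561 counted reads in replicates 1, 2 and 3, and the shNSUN2 libraries held 33756780, 27149125 and 30485030. Between 13527 and 14917 genes had at least 1 read per library, and 12230 genes had enough reads to be tested. The labels describe independent RNA extracts and do not say that the cultures were separate, so the p-values measure the spread between these samples, which may be technical.

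The silenced gene was examined first. NSUN2 (ENSG00000037474) stood at 259 ± 58.5 normalised read counts, as CPM, in scrambled cells and at 76.4 ± 8.13 in shNSUN2 cells (SD, n = 3), which is 29.4% of the control level. The individual values were 319, 257 and 202 CPM in the scrambled libraries and 85.7, 72.3 and 71.0 CPM in the shNSUN2 libraries. NSUN2 thus fell in each shNSUN2 library relative to each control, with a log2 fold change of -1.76 ± 0.18 (SE) and an adjusted p of 0.0255 by edgeR's quasi-likelihood test. The call was lost when scrambled replicate 1, scrambled replicate 2, shNSUN2 replicate 2 or shNSUN2 replicate 3 was left out (adjusted p of 0.210, 0.391, 0.462 and 0.182), while the log2 fold change stayed between -1.92 and -1.58.

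The main comparison asked which transcripts differ once NSUN2 is silenced. Besides NSUN2, 4 genes passed the 5% false discovery rate. ANXA1 (ENSG00000135046), which encodes the calcium-dependent phospholipid-binding protein annexin A1, rose from 102 ± 10.8 to 227 ± 16.9 CPM (SD, n = 3; log2 fold change 1.15 ± 0.12 SE, adjusted p = 0.0255). EFEMP1 (ENSG00000115380), which encodes the extracellular matrix glycoprotein fibulin-3, rose from 74.4 ± 5.74 to 162 ± 13.9 CPM (log2 fold change 1.12 ± 0.11, adjusted p = 0.0255). MZT1 (ENSG00000204899), a component of the gamma-tubulin ring complex that nucleates microtubules, rose from 98.8 ± 4.10 to 188 ± 5.76 CPM (log2 fold change 0.93 ± 0.09, adjusted p = 0.0255). OAZ1 (ENSG00000104904), which encodes ornithine decarboxylase antizyme 1, an inhibitor of polyamine synthesis, fell from 215 ± 19.6 to 105 ± 5.59 CPM (log2 fold change -1.03 ± 0.11, adjusted p = 0.0260). MZT1 has pseudogenes named after it, so its count is uncertain where reads could be shared with them.

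**Figure D1:**
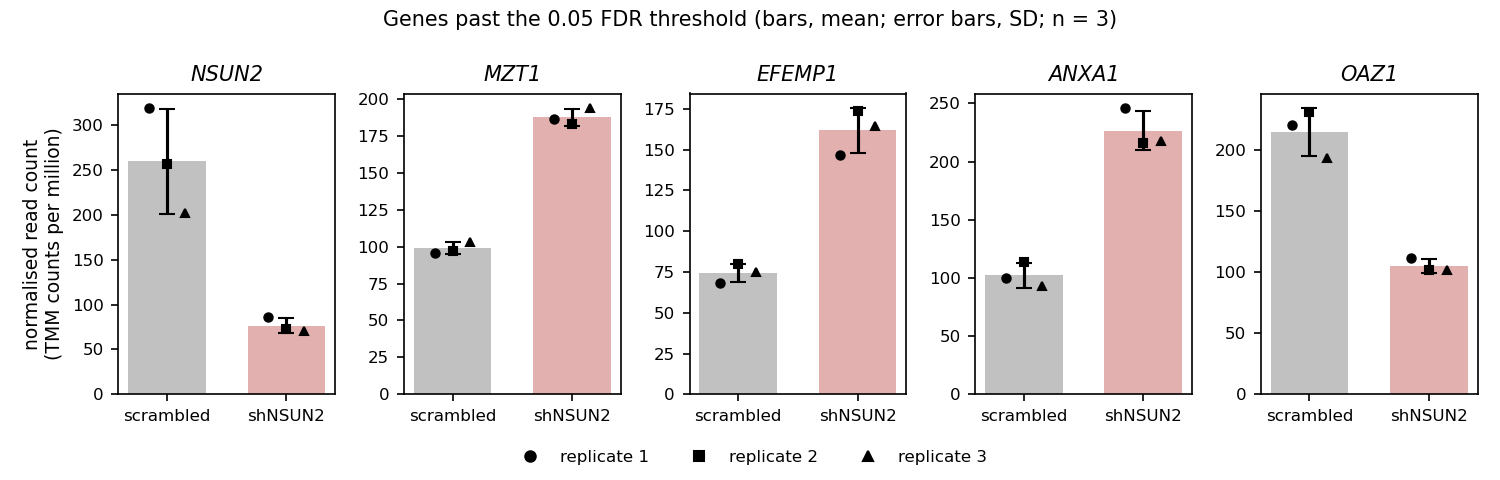
Normalised read counts (TMM-scaled CPM, vertical axis) of the 5 genes past the 0.05 false discovery rate in scrambled and shNSUN2 Jurkat libraries. Bars show the mean, error bars the SD (n = 3) and symbols the single libraries by replicate number. NSUN2 averaged 259 CPM in scrambled and 76.4 CPM in shNSUN2 cells, and the values of the groups did not overlap for any of the 5 genes.

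In all, 5 of 12230 genes passed, 3 higher and 2 lower in shNSUN2 cells, and 4 of them differed at least 2-fold. At an unadjusted p under 0.05, 444 genes stood out, 234 higher and 210 lower, against 612 expected by chance alone. The values of the groups did not overlap for 1184 genes (9.7%), where chance gives 10%. Scaling by library totals alone left 1 higher and 2 lower gene, with EFEMP1 and MZT1 no longer past the threshold (adjusted p = 0.0606 and 0.0599) at log2 fold changes of 1.12 and 0.93, the same as reported. No gene passed when scrambled replicate 1, scrambled replicate 2, shNSUN2 replicate 2 or shNSUN2 replicate 3 was left out (0 genes, with 322, 234, 297 and 469 genes at an unadjusted p under 0.05), NSUN2 alone passed without scrambled replicate 3, and the log2 fold changes of ANXA1, EFEMP1, MZT1 and OAZ1 with 1 library left out ran from 1.07 to 1.22, 1.06 to 1.17, 0.90 to 0.96 and -1.11 to -0.99. DESeq2 called 50 genes, 23 higher and 27 lower. With the replicate number as a block, 103 genes passed and 1527 had an unadjusted p under 0.05. A fit with 1 surrogate variable, chosen after seeing the data, gave 408 and 1931. The count of 444 thus depends on the model and does not show that few genes changed.

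Among the genes closest to the threshold, SDHD, which encodes a membrane anchor subunit of succinate dehydrogenase, stood at 80.02 ± 6.17 CPM in scrambled and 43.8 ± 1.37 CPM in shNSUN2 cells (SD, n = 3; log2 fold change -0.87 ± 0.11 SE, edgeR adjusted p = 0.107). NCOA7 measured 78.2 ± 0.749 and 45.3 ± 4.18 CPM (log2 fold change -0.79), and the septin gene SEPT11 measured 71.8 ± 2.44 and 43.7 ± 1.13 CPM (log2 fold change -0.72). On the higher side, the ubiquitin-specific protease gene USP13 measured 69.9 ± 4.01 and 116 ± 4.11 CPM (log2 fold change 0.73), and the septin gene SEPT2 measured 339 ± 20.6 and 565 ± 47.3 CPM (log2 fold change 0.74). None of these 5 passed edgeR's quasi-likelihood test with the group alone in the model (adjusted p from 0.107 to 0.166). Each lay past the threshold with DESeq2, and in the quasi-likelihood test with the replicate number as a block (adjusted p from 0.000544 to 0.00226). In the simulated sets DESeq2 made 218 false calls, against 48 for the quasi-likelihood test with the group alone. SDHD and SEPT2 also have pseudogenes named after them.

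Gene groups fixed in advance were then compared with all other genes. Of 26 lists tested with camera, 4 passed at a preset inter-gene correlation of 0.01, 1 higher and 3 lower in shNSUN2 cells. Interferon-stimulated genes rose as a list: 30 of 41 tested members had a log2 fold change above 0, the median was 0.17, and the adjusted p was 0.00111. With an estimated correlation the list had an adjusted p = 0.926, and without scrambled replicate 1 an adjusted p = 0.0611 at an unmoved median of 0.17. Without shNSUN2 replicate 1 the median was 0.28. No single member passed edgeR's quasi-likelihood test over all genes or when adjusted over the list alone, 1 (IFIT3) passed with DESeq2 and with edgeR's exact test, and 8 members were higher and 1 lower at an unadjusted p under 0.05. The antiviral gene IFIT3 measured 4.21 ± 0.9002 CPM in scrambled and 9.26 ± 1.44 CPM in shNSUN2 cells (SD, n = 3; log2 fold change 1.14), and XAF1 measured 94.7 ± 2.31 and 122 ± 13.2 CPM (log2 fold change 0.36). MX2, which encodes an interferon-induced GTPase, went the other way, at 8.42 ± 1.58 and 4.29 ± 0.915 CPM (log2 fold change -0.97). XAF1 was picked after its values were seen.

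Targets of ATF4, the transcription factor that supplies amino acids under stress, fell as a list: 26 of 33 tested members lay below 0, with a median log2 fold change of -0.17 and an adjusted p of 0.00172 (adjusted p = 0.926 with an estimated correlation). The arginine transporter gene SLC7A1 measured 232 ± 32.9 and 156 ± 23.2 CPM in scrambled and shNSUN2 cells (SD, n = 3; log2 fold change -0.57), and PHGDH, the entry enzyme of serine synthesis, measured 90.8 ± 7.85 and 67.3 ± 8.95 CPM (log2 fold change -0.43). Cholesterol synthesis genes fell as a list as well, with 22 of 25 below 0, a median of -0.15 and an adjusted p of 0.00766 (adjusted p = 0.949 with an estimated correlation). The sterol reductase gene DHCR7 had a log2 fold change of -0.35. The cytosolic ribosomal protein genes fell by a small amount, with 59 of 77 below 0, a median of -0.06 and an adjusted p of 0.00443 (adjusted p = 0.949 with an estimated correlation). RPL23A measured 623 ± 54.6 and 404 ± 44.2 CPM (log2 fold change -0.63), RPL18 had a log2 fold change of -0.31, and these genes have many processed pseudogenes, so their counts are uncertain. No member of the ATF4, cholesterol or ribosomal lists passed edgeR's quasi-likelihood test over all genes or when adjusted over the list alone. With DESeq2 and with edgeR's exact test, 1 ribosomal protein gene (RPL23A) and 0 genes of the other lists passed. At an unadjusted quasi-likelihood p under 0.05 there were 5 lower ATF4 targets, 2 lower cholesterol genes, and 6 lower and 1 higher ribosomal protein genes. On the log2 CPM scale, the ATF4 median of -0.18 became -0.08 without scrambled replicate 3 and -0.16 without shNSUN2 replicate 2, and the call was lost in both cases (adjusted p = 0.0672 and 0.125). The ribosomal median of -0.06 became -0.05 without scrambled replicate 1 and -0.03 without shNSUN2 replicate 2, where the call was lost (adjusted p = 0.263 and 0.543), and -0.11 and -0.12 without scrambled replicate 3 and shNSUN2 replicate 1. The cholesterol median of -0.17 became -0.06, -0.03 and -0.19 without scrambled replicate 3, shNSUN2 replicate 1 and shNSUN2 replicate 2, where the call was lost (adjusted p = 0.559, 0.478 and 0.0580), and -0.27 and -0.31 without scrambled replicate 1 and shNSUN2 replicate 3.

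**Figure D2:**
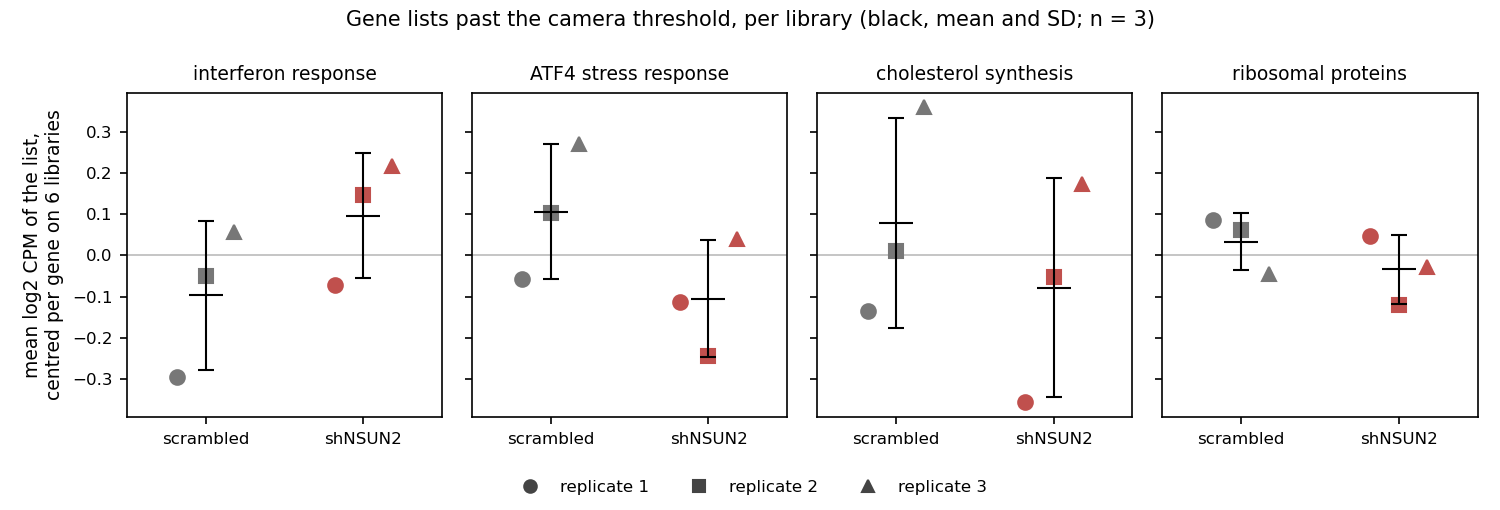
Mean log2 CPM of the members of the 4 gene lists past the camera threshold, centred per gene on the 6 libraries (vertical axis), for each scrambled and shNSUN2 library. Symbols give the replicate number and black marks the mean and SD (n = 3). Interferon-response levels were -0.296, -0.051 and 0.057 in scrambled and -0.073, 0.146 and 0.218 in shNSUN2 libraries, so the groups overlapped.

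Genes tied to the biology of NSUN2 did not pass. The other RNA 5-methylcytosine writers, erasers and readers had 7 of 15 tested members above 0, with an adjusted p of 0.712 for the list. Their median log2 fold change was -0.05, while the mean was 0.05 and the test pointed up. The member with the smallest p was the splicing factor gene SRSF2, at 39.9 ± 4.63 and 50.3 ± 4.74 CPM in scrambled and shNSUN2 cells (SD, n = 3; log2 fold change 0.33), followed by FMR1 with a log2 fold change of 0.40. Transcripts described elsewhere as NSUN2 substrates had 3 of 12 members above 0 and an adjusted p of 0.717. CDK1, the mitotic kinase, measured 30.0 ± 0.937 and 34.9 ± 2.80 CPM (log2 fold change 0.22), and the CDK inhibitor gene CDKN1A measured 2.13 ± 0.421 and 1.36 ± 0.751 CPM. Other tRNA-modifying enzymes (adjusted p = 0.875, with DUS1L at -0.31 and CDKAL1 at 0.22) and cytosolic tRNA synthetases (adjusted p = 0.712, with MARS at -0.18 and VARS at -0.25) did not pass either. For the tRNA-modifying enzymes the median was 0.04 and the mean -0.004. Without shNSUN2 replicate 1 the tRNA-modifying enzymes and the synthetases were called lower (medians -0.14 and -0.10 on the log2 CPM scale, adjusted p = 0.0327 and 0.0389), and without shNSUN2 replicate 3 the medians were 0.13 and 0.002, with no call (adjusted p = 0.0736 and 0.714).

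T-cell and leukaemia genes gave no passing list with all 6 libraries and the filter used. T-cell receptor and proximal signalling genes had 18 of 26 tested members below 0 (adjusted p = 0.182). In scrambled and shNSUN2 cells the adhesion receptor gene CD2 measured 164 ± 9.94 and 134 ± 9.28 CPM, and the phospholipase gene PLCG1 measured 278 ± 17.96 and 231 ± 17.3 CPM (SD, n = 3). Among transcription factors of immature T cells (19 of 31 below 0, adjusted p = 0.664), RUNX1 had a log2 fold change of -0.28 and LEF1 one of -0.36. NOTCH targets had 12 of 18 members above 0 (adjusted p = 0.135), with CR2 at 0.75 and DTX1 at 0.73. The NOTCH list was called higher with a filter of 1 CPM in 3 libraries (median 0.15, adjusted p = 0.0481) and without shNSUN2 replicate 3 (median 0.32, adjusted p = 0.0289), with a median of 0.15 as reported. Without shNSUN2 replicate 1, shNSUN2 replicate 2 or scrambled replicate 3 the median fell to 0.04, 0.03 and 0.06, with no call (adjusted p = 0.465, 0.301 and 0.276). None of the genes reported here as controls of this line passed edgeR's quasi-likelihood test. MYC had a log2 fold change of -0.26 ± 0.40 (SE), NOTCH1 0.13 ± 0.15 and BCL2 -0.14 ± 0.11.

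Proliferation and metabolism were also measured. Genes of G2 phase and mitosis had 29 of 46 members above 0 (adjusted p = 0.0708). The list was called higher with a filter of 1 CPM in 3 libraries (adjusted p = 0.0481) and without scrambled replicate 1 (0.00497). Leaving out any other library gave no call, with an adjusted p of up to 0.4375 (without scrambled replicate 2). The median was then 0.04 to 0.06 on the log2 CPM scale, against 0.08 with all libraries. PRC1, which bundles microtubules of the central spindle, measured 167 ± 10.9 and 249 ± 28.2 CPM in scrambled and shNSUN2 cells (SD, n = 3, log2 fold change 0.58). PRC1 was the 1 member that passed when adjusted over the list alone. DNA replication genes had 19 of 42 members above 0 (adjusted p = 0.877, median -0.01 while the test pointed up), with the helicase subunit gene MCM6 at 0.38 and E2F2 at -0.43. Apoptosis genes (adjusted p = 0.877) and p53 targets with CDK inhibitors (adjusted p = 0.712) did not pass. In the hypoxia list (adjusted p = 0.523), ERO1L, which encodes an endoplasmic reticulum oxidase, had a log2 fold change of 0.70 and EGLN3, which encodes a prolyl hydroxylase that acts on HIF, one of -1.01. Both passed when adjusted over the list alone, and limma's fry gave the list an adjusted p of 0.0272 for change in either direction. Among respiratory chain subunits (32 of 66 above 0, adjusted p = 0.684), SDHD passed when adjusted over the list alone. Without shNSUN2 replicate 1 the respiratory chain was called lower, at a median of -0.12 on the log2 CPM scale (adjusted p = 0.00187), and its other medians with 1 library left out ran from -0.07 to 0.04. Glycolytic enzymes had 9 of 24 members above 0 (adjusted p = 0.712).

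The libraries of a single group differed from each other along a shared axis. The first principal component held 43.8% of the variance and placed scrambled replicates 1, 2 and 3 at -33.7, -2.46 and 30.3, and shNSUN2 replicates 1, 2 and 3 at -49.5, 21.7 and 33.7. Mean levels of MYC targets of ribosome biogenesis were 0.471, 0.152 and -0.453 (log2) in the scrambled libraries and 0.650, -0.261 and -0.560 in the shNSUN2 libraries, a range of 1.21. Heat-shock chaperones ranged over 0.857 in the same order, and immediate early genes ranged over 1.43, with their lowest levels in shNSUN2 replicate 1 (-0.81) and scrambled replicate 1 (-0.365). The interferon, ATF4 and cholesterol lists ranged over 0.514, 0.515 and 0.717 across the 6 libraries. Between groups, the MYC-target (adjusted p = 0.490), heat-shock (adjusted p = 0.523) and immediate early (adjusted p = 0.159) lists did not pass. Without scrambled replicate 3 or shNSUN2 replicate 1, the MYC targets (adjusted p = 0.000455 and 4.42e-06) and the heat-shock chaperones (adjusted p = 0.0106 and 0.0249) were called lower. Immediate early genes were called lower without scrambled replicate 1 or shNSUN2 replicate 3 (adjusted p = 0.00497 and 0.00684). With 1 library left out, the medians of these 3 lists ran from -0.42 to 0.20, -0.35 to 0.22 and -0.50 to 0.17 on the log2 CPM scale, so their direction turned.

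**Figure D3:**
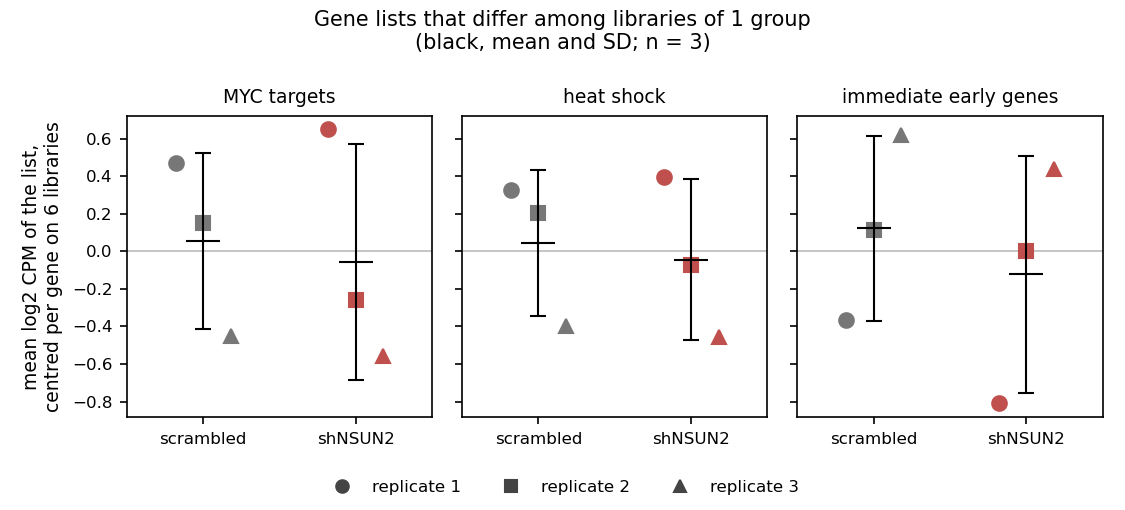
Mean log2 CPM of MYC targets of ribosome biogenesis, heat-shock chaperones and immediate early genes, centred per gene on the 6 libraries (vertical axis), in each scrambled and shNSUN2 library. Symbols give the replicate number and black marks the mean and SD (n = 3). MYC targets ranged over 1.21 and immediate early genes over 1.43, and the groups overlapped in each list.

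Few markers of B cells, myeloid cells, erythroid cells, epithelial cells and fibroblasts had enough reads to be tested. Of the marker genes for B cells, 3 could be tested, and the kinase gene BLK measured 17.6 ± 1.07 and 11.7 ± 0.175 CPM in scrambled and shNSUN2 cells (SD, n = 3). BLK passed edgeR's quasi-likelihood test when adjusted over the list alone and not over all genes, where DESeq2 gave an adjusted p of 0.0481, and CD79A had a log2 fold change of -0.38. For myeloid cells 2 markers, for epithelial cells and fibroblasts 2, and for erythroid cells 0 could be tested, and the myeloid markers CD33 and ITGAM had group means under 0.7 CPM. Natural killer and cytotoxic markers (11 tested, adjusted p = 0.523) had a median log2 fold change of 0.06 and a mean of -0.18.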

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

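The exact test, the surrogate variable and leaving out both libraries of 1 number were chosen after seeing the data. NSUN2, ANXA1, EFEMP1, MZT1 and OAZ1, the 5 called genes, were all among the calls with DESeq2 size factors, no low-count filter, a filter of 1 CPM, DESeq2, limma-voom, the exact test and the surrogate variable. DESeq2 gave 50 genes (23 higher, 27 lower, 16 at least 2-fold), the exact test 36 (19, 17 and 16) and the surrogate variable 408 (196, 212 and 39). Library totals alone gave 3 (1 higher), no filter 4 lower genes, and a threshold of 0.01 gave 0 in the quasi-likelihood test. The causes were not tested. Leaving out 1 library gave 0 to 5 genes, 0 to 3 higher, 0 to 2 lower and 0 to 4 at least 2-fold, with fewer samples in each fit, and the NSUN2 log2 fold change ran from -1.92 to -1.58. Without both libraries numbered 2, or both numbered 3, 0 genes passed in the quasi-likelihood test (129 and 340 at an unadjusted p under 0.05), with NSUN2 at -1.74 and -1.87 and not past the threshold. Without both numbered 1, the same 5 genes passed.

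Whether the shared replicate numbers pair the samples is not settled. Deviations from the group means correlated at 0.487, 0.034 and 0.490 for numbers 1, 2 and 3. Scrambled replicate 1 with shNSUN2 replicate 3 gave -0.412, and scrambled replicate 3 with shNSUN2 replicate 1 gave -0.536. Scrambled replicate 2 correlated little with shNSUN2 replicates 1, 2 and 3 (0.042, 0.034 and -0.084). That library lay near the middle of its group on the first principal component (-2.46, against -33.7 and 30.3). Its low correlations therefore cannot argue against a pairing. A pairing was not established either, and the block stayed an alternative. With the number as a block, 103 genes passed (62 higher, 41 lower, 19 at least 2-fold), the 5 above and SDHD, USP13, SEPT2, NCOA7 and SEPT11 (adjusted p from 0.000544 to 0.00226) among them. Those 5 also passed the exact test (adjusted p from 2.25e-05 to 0.00119), which made 194 false calls in the simulated sets, against 48 for the quasi-likelihood test. With the block, camera called immediate early genes lower (adjusted p = 0.0492).

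Leaving out 1 library gave 1 to 9 passing lists (9 without shNSUN2 replicate 1, 1 without shNSUN2 replicate 2), leaving out both libraries numbered 1 or 2 gave 8 and 2, and an estimated correlation or fry's test of 1 direction gave 0. Fry's test of change in either direction called 1 list, the hypoxia targets. Without both libraries numbered 1, MYC targets, the respiratory chain and the unfolded protein response were called lower and G2 and mitosis genes higher (adjusted p = 0.00710, 0.0222, 0.0231 and 0.0222). Without shNSUN2 replicate 1 the tRNA-modifying enzymes were called lower (median -0.14 on the log2 CPM scale), while the reported test pointed up without a call, and their other medians with 1 library left out reached 0.13. Over 1238 values of named genes besides NSUN2, 1120 kept sign and side of the threshold, 68 newly passed, 30 no longer passed and 20, of 5 genes with no call either way, differed in sign. Of these 69 genes only ANXA1, EFEMP1, MZT1 and OAZ1 were called as reported, and all 30 losses were theirs. Most of the 1120 values are of genes that were not called in either fit, so they do not show that the calls are stable. Simulated sets of this depth and number of libraries held 12230 genes. In genes with a mean over 100 reads, edgeR recovered 15.6% of 1.5-fold and 66.0% of 2-fold changes. Those genes varied independently and 200 per set were changed, while the real libraries share an axis across the groups. The figures thus do not give the recovery in the real data, and changes that were not called cannot be excluded.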

Other observations

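The fit with the estimated correlation was planned, and its use below, and that of other splits, to weigh explanations for the interferon genes was chosen after those results were seen. Besides the genes named so far, IGF2R and RHOT1 lay at a quasi-likelihood adjusted p under 0.2, picked here after their values were seen. IGF2R, which encodes the receptor that carries lysosomal enzymes, measured 516 ± 59.9 CPM in scrambled and 288 ± 32.2 CPM in shNSUN2 cells (SD, n = 3; log2 fold change -0.84, adjusted p = 0.176). RHOT1, which encodes a mitochondrial outer membrane GTPase, measured 123 ± 5.83 and 73.8 ± 7.63 CPM (log2 fold change -0.74, adjusted p = 0.184). Scrambled replicate 3 had 14917 genes with at least 1 read, and the other 5 libraries had 13527 to 14109.

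The remaining lists did not pass camera: the unfolded protein response (adjusted p = 0.283, and 0.00208 without shNSUN2 replicate 1, where it was called lower), NF-kB targets (0.752, with a median of 0.001 and a mean of -0.02), FOXO and KLF2 targets (0.775, with a median of 0.02 and a test that pointed down) and replication-dependent histones (0.684). The histone genes, whose mRNAs lack poly(A) tails, had means over the libraries of at most 5.13 CPM (scaled by library totals). Their list thus rests on weakly detected genes. On the log2 CPM scale the unfolded protein response had a median of -0.08, and -0.26 without shNSUN2 replicate 1. Its other medians with 1 library left out ran from -0.17 (without scrambled replicate 3) to 0.03 (without shNSUN2 replicate 3), with no call. TXNIP, a FOXO target, measured 1.25 ± 0.943 and 3.29 ± 1.94 CPM in scrambled and shNSUN2 cells, and the phosphatase gene DUSP1, an immediate early gene, 16.1 ± 3.22 and 10.02 ± 2.08 CPM (SD, n = 3).

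The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5 genes, and 2 of the 10 splits, the real one included, gave at least as many, the highest of the others 2411. The same held for 3 higher and 2 lower genes (2 of 10 splits each, highest other 1319) and for 4 genes at least 2-fold (2 of 10, highest other 264). The split that called 2411 genes set scrambled replicates 1 and 2 with shNSUN2 replicate 1 against the rest, which points to a structure of the samples that the groups do not explain. For the 4 lists, 7 of 10 splits, the real one included, gave at least as many, and the highest other gave 13.

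MYC targets and heat-shock chaperones differed between libraries of 1 group by up to 1.21 and 0.857 (log2). After correction for GC content and length at least 106% of the range stayed, which argues against GC or length bias. Thinning all libraries to 27149125 reads kept at least 99.7%, but no total exceeded 36847621, so thinning could move little. Scrambled replicate 3 and shNSUN2 replicate 1 held 33250561 and 33756780 reads. Their MYC-target levels were -0.453 and 0.650 and their heat-shock levels -0.399 and 0.399, which argues against depth for these libraries. The 100 most abundant genes outside the lists took 13.8% to 14.5% of the reads, which allows a shift of 0.011, far below the range. The labels give no batch, culture or time that separates these libraries, so no biological explanation was tested and the difference stays unexplained.

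The 9 genes besides NSUN2 with the smallest p (MZT1, EFEMP1, ANXA1, OAZ1, SDHD, USP13, SEPT2, NCOA7 and SEPT11) kept 97.0% of their median absolute log2 fold change after correction for GC content and length. That correction moved the log2 fold changes of all genes by a median of 0.032, so it could take little from genes picked for large differences. Of these 9, 3 (MZT1, SDHD and SEPT2) have a pseudogene named after them, so pseudogenes named in this way cannot account for the whole set. Pseudogenes under other names, paralogs and the mapping of reads were not examined, so shared reads are not excluded for any of the 9. An unintended effect of the hairpin (#2 in the labels) could be another explanation. The 7-base word whose presence in 3' untranslated regions went with the lowest fold changes had a z of -4.05, against -4.44 at the 95th percentile of 100 shuffles. The 9 other splits, which have no direction of their own, gave a median of -4.01 over their lowest z and their highest z with the sign turned, and of -3.89 over the lowest z alone. The word is not in the NSUN2 mRNA, and 0 of the 4 lowered genes among the 9 hold it. Few targets would not move such a score, and the hairpin's sequence was not used here, so effects of the hairpin cannot be told apart from those of NSUN2 loss for these genes.

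Interferon-response genes lay higher in shNSUN2 cells, with a median log2 fold change of 0.17. The median did not rest on 1 library, since the medians with 1 library left out ran from 0.166 to 0.282 (without shNSUN2 replicate 1). The call ended without scrambled replicate 1 (adjusted p = 0.0611). That library had the lowest mean level of the list, -0.296 against -0.051 and 0.057 in scrambled replicates 2 and 3. The difference in mean level thus rested in part on it. A structure of the samples is not excluded, since the split that called 2411 genes gave this list a larger median (0.217, adjusted p = 0.0251) and the split of scrambled replicates 1 and 3 with shNSUN2 replicate 1 against the rest gave 0.135 (adjusted p = 0.00238). With a correlation estimated from the data (0.152) camera gave an adjusted p of 0.926 and an unadjusted p of 0.142. Members that vary together by chance may thus produce such a shift, and an effect of NSUN2 loss stays open as well.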
